A study of Homo sapiens with 6 samples.

How the data were processed

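Total RNA from MEL1 human ES cells and from the same line after 3 days of endoderm induction was made into libraries with an Illumina TruSeq RNA kit after column extraction, per the labels' protocols, with 3 libraries per group. The submitters' processing notes name bcl2fastq, Trim Galore 0.4, STAR 2.6, featureCounts 1.4.6 of Subread and DESeq2, with hg19 as the genome build, and give no order or settings. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Antisense genes, overlapping genes and near-identical paralogs are therefore uncertain.

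The authors deposited a table of raw read counts per gene symbol for the 6 libraries. It holds 27317 symbols, of which 4907 have no count in any library, and no row for reads outside genes. The counts sum to 24254755 to 36393026 per library, so 1 count is worth 0.0275 to 0.0412 CPM. The authors also deposited a table of log2 values from DESeq2. Its name speaks of normalized counts, but its values run from -2.21 to 18.6 and fit a log2 scale that is shrunken at low counts. Among the 4907 genes without a count, 827 have a value other than 0 there, so this table was not used for any test. For the 11572 genes called below, the difference between group means in the deposited log2 table had the same sign as the fitted log2 fold change in 100% of genes, with a slope of 0.538 across them.

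Samples were assigned to groups by their titles, and all 6 entered each fit except those that leave out a library. Genes with few counts were removed with filterByExpr of edgeR 4.0.16 (minimum count of 10), which left 16331 genes holding 99.95% of all counts. Library sizes were scaled by TMM, and ES cells and endoderm were compared with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, robust, two-sided, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. SE values of log2 fold changes were computed from the fold change and its F statistic. Where the fold is large and a group has few counts, such values understate the error. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Fold changes of genes with a group at 0 were computed against a floor of 3 counts over the group, and those with 1 to 3 counts are given as a ratio with an exact 95% interval. Intervals and floors cover counting error only. Changes given for a gene without a unit are log2 fold changes of endoderm over ES cells.

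Before the data were examined, 35 gene lists were written down, along with the tests, the alternatives and the rule for named genes. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean CPM of at least 10 in the higher group and no overlap between groups, leaving out XIST and Y-linked genes. It adds a fixed panel of 28 markers. It also takes, from each list, up to 3 highest and 3 lowest members past the threshold and the 2 most abundant that did not pass. Of the list members so taken, only a part is printed below, and members with larger changes can be missing. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 33 lists. Camera asks whether a list's genes rank above or below the other genes, whereas fry asks whether they move on balance in one direction.

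The fit was tested on simulated counts drawn from the ES means, the real library sizes and the fitted dispersions, in which 200 genes were changed. For endoderm against ES, with 15830 genes tested, 40% of the genes changed by 1.2-fold were recovered, 80% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, and 5 unchanged genes were called. Camera found a list of 25 genes shifted by 1.5-fold and called 0 of 35 lists without a shift. Genes were drawn independently of each other, whereas estimated correlations within the real lists reached 0.517. The simulation therefore does not show how often camera calls unshifted lists of correlated genes. It also changed 200 genes by at most 4-fold, whereas 70.9% of tested genes passed the threshold in the data. The p-value that the adjustment lets pass and the spread of the other genes thus differ. The shares recovered, the 5 calls and the camera result do not carry over to the data. The fold sizes and the list length of this simulation were changed after earlier runs of it had been seen. Alternatives were DESeq2 1.42.0 as the test, its size factors in edgeR, library size alone, no filter, a mean CPM of at least 5, the replicate number as a block, an adjusted p of 0.01, leaving out the 20 most abundant genes, leaving out each library, and a test against a fold of 2. The reference given for this work is GRCh38, another build than that of the files, so no coordinates are printed and it was used only for transcript lengths matched by symbol, which 95.4% of tested genes had.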

Results

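RNA-seq gene counts were examined for 6 libraries of MEL1, an established human embryonic stem (ES) cell line. In 3 libraries the cells were kept as ES cells in a defined medium on a basement membrane matrix. In the other 3 they had been taken through 3 days of a commercial endoderm induction. Endoderm is the germ layer that gives rise to the gut tube, liver, lung and pancreas. The counts of the ES libraries summed to 24254755, 28905489 and 30954296 for replicates 1 to 3, and those of the endoderm libraries to 31583008, 36393026 and 24607155. At these totals 1 count equals 0.0275 to 0.0412 CPM (counts scaled to library size). The most abundant transcript took 1.16 to 1.37% of each library, so no library was dominated by a few genes. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

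The comparison asks which transcripts differ between ES cells and their endoderm derivatives. The groups stood far apart. The first principal component of log2 CPM held 92.2% of the variance, with the ES libraries between -73.3 and -71.0 and the endoderm libraries between 70.6 and 73.9. Across genes, log2 CPM correlated at 0.993 to 0.996 (Pearson) within a group and at 0.911 to 0.916 between groups. No pair of libraries in a group agreed within sampling noise. Chi-square values were 2.01 to 7.42 per degree of freedom within groups, against 152 to 202 between them. Pairs with ES replicate 2 (7.42 and 6.81) and with endoderm replicate 1 (5.58 and 5.49) agreed least in their groups. Of 16331 genes tested, 5821 were higher and 5751 lower in endoderm at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Over 2-fold, 1743 were higher and 1745 lower. The largest changes lay on the rising side, where 229 genes rose by over 16-fold while 73 fell by as much. The groups did not overlap for 73.3% of tested genes, where chance gives 10%.

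Among the 10 named genes with the largest rise were transcription factors, secreted factors, a cell surface glycoprotein and 2 noncoding RNAs. SOX17, an endoderm transcription factor, went from 0.145 ± 0.152 to 312 ± 34.8 CPM (mean ± SD, n = 3 per group, as below), a log2 fold change of 10.96 ± 0.18 (SE). GATA6 rose by 10.46 ± 0.16, the T-box factor EOMES by 9.91 ± 0.13, the LIM homeobox factor LHX1 by 10.08 ± 0.12 and the growth factor FGF17 by 10.67 ± 0.12. CER1, a secreted inhibitor of NODAL, BMP and WNT, went from 10.2 ± 2.5 to 7069 ± 215 CPM and then made up 0.672 to 0.713% of all counts. DKK4, a secreted WNT inhibitor, reached 659 ± 24.8 CPM with a log2 fold change of 11.11 ± 0.34. CD48, a cell surface glycoprotein, went from 0.0705 ± 0.0323 to 34.2 ± 4.1 CPM. LINC00479 had no count in any ES library and 17.8 ± 0.7 CPM in endoderm, at least 507-fold higher against a floor of 3 counts over the group. GATA6-AS1 had 2 counts over the ES libraries, which gives a ratio of 2586 with a 95% counting interval of 716 to 21362. Its reads cannot be told from those of GATA6 without a stated strand setting.

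The ES levels behind the largest folds rested on few counts, and most of these came from ES replicate 3. SOX17 had 2, 1 and 10 counts in ES replicates 1 to 3, GATA6 had 2, 3 and 18, EOMES 17, 10 and 38, and DKK4 1, 0 and 24. Without ES replicate 3 the log2 fold changes were 11.95 for GATA6 and 10.50 for EOMES. SOX17 and DKK4 then had 3 and 1 ES counts, which give ratios of 5624 (95% counting interval 1924 to 27275) and 35563 (6383 to 1404700). GATA6-AS1 then had no ES count and was at least 1088-fold higher against a floor of 3 counts over the group. DKK4 stood at 10.51 without ES replicate 2. All of these remained past the threshold, so the sizes of these folds, not their direction, depended on that library. The SE values given above for the genes with the largest rise understate the error left by few ES counts. Without ES replicate 3, GATA6 and EOMES moved by more than their SE.

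**Figure D1:**
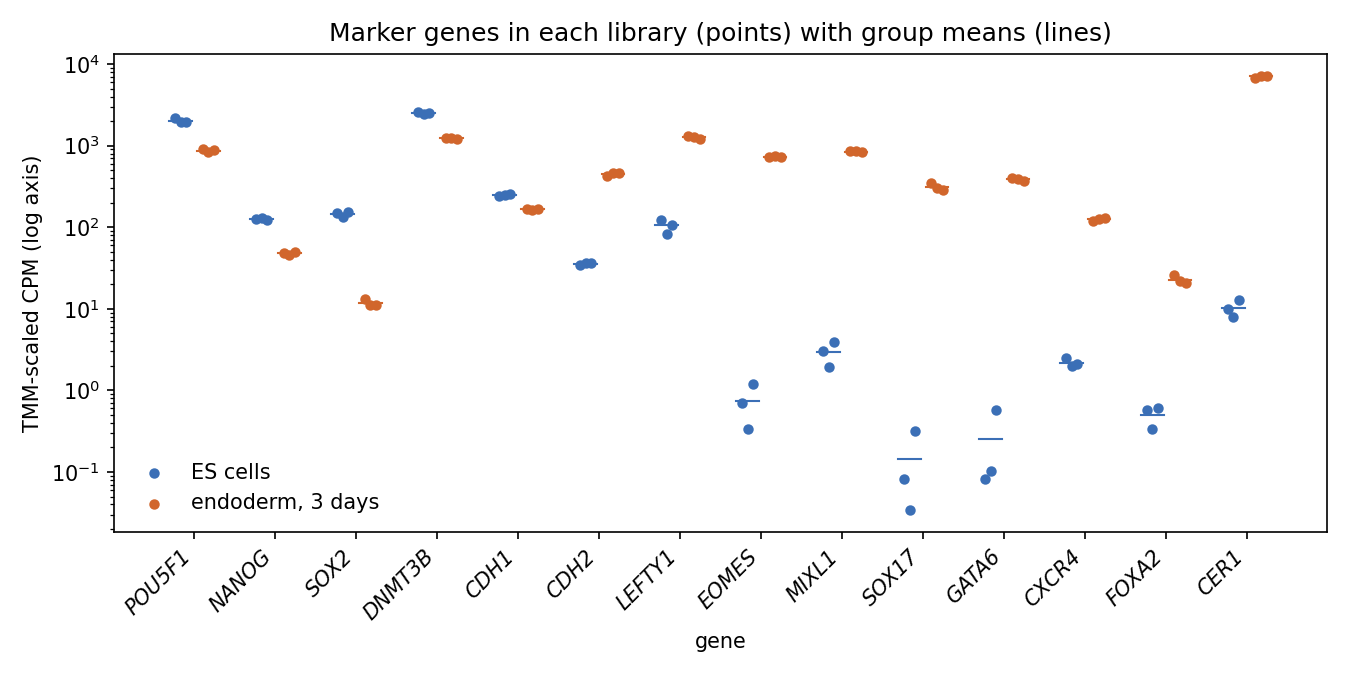
TMM-scaled CPM on a log axis for 14 genes of the fixed panel, with a point per library (ES in blue, endoderm in orange) and a line at each group mean of 3. EOMES, SOX17, GATA6 and CER1 lie orders of magnitude apart between the groups, POU5F1 and CDH1 move by 2.32 and 1.49-fold, and among the low ES values of EOMES, SOX17 and GATA6 the highest point is ES replicate 3.

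The genes that fell most included IDO1, a tryptophan-degrading enzyme, from 30.0 ± 0.7 to 0.213 ± 0.042 CPM. UTF1, a chromatin factor of undifferentiated ES cells, went from 82.3 ± 23.2 to 1.19 ± 0.61 CPM. The metal-binding metallothioneins MT1H, MT1G and MT1E fell (log2 fold changes of -6.59, -5.52 and -5.46), and their near-identical copies leave the split of reads between them uncertain. LINC00599, the membrane proteins TTYH1 and SLC38A4, the sphingolipid synthesis subunit SPTSSB and the interferon-inducible TRIM22 fell, with log2 fold changes of -5.51 to -4.79.

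Pluripotency genes fell unevenly. Of 48 tested members, 37 fell, 8 rose and 3 did not pass (median log2 fold change -1.37). SOX2 dropped 12.3-fold, from 146 ± 10.2 to 11.9 ± 1.3 CPM, and VSNL1 and DPPA5 fell (log2 fold changes of -3.65 and -4.32). The core factor POU5F1 remained abundant, at 2023 ± 117 CPM in ES cells and 872 ± 32.0 in endoderm. The log2 fold change was -1.40 ± 0.05 (SE) for NANOG, -1.03 ± 0.03 for the de novo methyltransferase DNMT3B, -0.47 ± 0.03 for the RNA-binding protein LIN28A and -0.41 ± 0.04 for ZFP42. POU5F1 has processed pseudogenes, so its count could include or lose shared reads. TBX3, OTX2 and KLF5 rose by 5.69, 3.71 and 2.24. OTX2 is also a factor of the anterior embryo. SALL4 (0.08 ± 0.04 SE) and SALL1 (-0.04 ± 0.05) did not pass. The list as a whole lay below other genes with a preset correlation (camera, adjusted p = 5.94e-07), with adjusted p = 0.19 with an estimated correlation.

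Primitive streak and mesendoderm genes rose almost without exception. Of 18 tested members, 17 rose and none fell (median 6.66), led by FGF17, LHX1 and EOMES. MIXL1 went from 2.98 ± 0.99 to 848 ± 11.9 CPM, T (brachyury) from 0.139 ± 0.046 to 41.3 ± 3.5 and GSC from 0.413 ± 0.270 to 134 ± 11.9. GSC rose by 8.26 on the log2 scale, or 8.89 without ES replicate 3. MESP2 did not pass, at 0.985 ± 0.152 and 0.989 ± 0.503 CPM. Its paralog MESP1, from the fixed panel, was at 0.670 ± 0.353 and 1.21 ± 0.06 CPM with an adjusted p of 0.024 (edgeR), which rose to 0.11 without ES replicate 2, 0.053 without endoderm replicate 1 and 0.051 without endoderm replicate 3. The list gave a camera adjusted p of 1.56e-07, with adjusted p = 0.32 with an estimated correlation. It shares 5 genes with the definitive endoderm list, so these lists are not separate evidence.

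Most definitive endoderm markers rose. Of 46 tested members, 41 rose, 2 fell and 3 did not pass (median 3.69). The pioneer factor FOXA2 went from 0.506 ± 0.144 to 22.8 ± 2.5 CPM and GATA4 from 1.07 ± 0.40 to 101 ± 4.2. The chemokine receptor CXCR4, used to sort endoderm, went from 2.18 ± 0.25 to 125 ± 6.0 CPM and HHEX from 0.505 ± 0.162 to 12.5 ± 0.04. TMPRSS2 fell by 0.96 and VIL1 fell by 0.44. The VIL1 call was lost without ES replicate 1 (adjusted p = 0.091, edgeR) and without endoderm replicate 2 (0.089). KLF3 (0.06 ± 0.06 SE) and FOXA3 (0.02 ± 0.08) did not pass. The camera adjusted p was 3.27e-14, with adjusted p = 0.19 with an estimated correlation. The list of primitive, visceral and parietal endoderm shares 4 genes with this list. In it 17 of 24 tested members rose and 3 fell (median 0.72, camera adjusted p = 0.00071, and adjusted p = 0.19 with an estimated correlation). BMP2 rose by 7.98, SOX7 went from 1.94 ± 0.22 to 6.09 ± 0.47 CPM, and APOB, NID2 and FST fell (log2 fold changes of -1.10, -0.64 and -0.64). The laminin subunit LAMC1 stood at 290 ± 8.8 and 287 ± 6.6 CPM and did not pass.

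Few markers of later gut organs were detectable. Only 11 of 30 members had enough counts to be tested, of which 6 rose and 2 fell (median 0.60, camera adjusted p = 0.17). The hepatic nuclear receptor HNF4A went from 0.0787 ± 0.0440 to 16.4 ± 0.5 CPM, while ONECUT1 fell by 2.58. SOX9 (4.21 ± 1.10 and 3.23 ± 0.61 CPM) did not pass, but did so as lower in endoderm without ES replicate 1 (adjusted p = 0.0065, edgeR) and without endoderm replicate 3 (0.032). AFP, the fetal liver secreted protein, and the hindgut factor CDX2 were too low to test. AFP had 12, 10 and 6 counts in the ES libraries and 4, 3 and 0 in endoderm, and CDX2 had at most 4 in any library.

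Markers of other lineages moved in both directions and mostly at low levels. Among mesoderm genes 13 of 19 tested members rose and 4 fell (median 0.56, camera adjusted p = 0.058). The list passed without ES replicate 1, endoderm replicate 2 or endoderm replicate 3 (camera adjusted p of 0.032, 0.049 and 0.047), and with all 6 libraries had an adjusted p of 0.44 with an estimated correlation. PDGFRA, a receptor of mesoderm and primitive endoderm, went from 1.98 ± 0.17 to 72.0 ± 4.8 CPM, and TBX20 and FOXC1 rose by 4.90 and 3.62. SNAI3 and TNNT2 fell (log2 fold changes of -3.24 and -1.62), and KDR did not pass at 59.6 ± 1.6 and 62.6 ± 0.9 CPM. HAND1 was too low to test, with at most 9 counts in a library. Among neuroectoderm genes 8 of 17 rose and 6 fell. Their median was 0.14 and their mean -0.60, and camera gave an upward adjusted p of 0.71. ZIC2 rose by 2.84 while POU3F1 and SOX1 fell (log2 fold changes of -3.79 and -3.80). Without endoderm replicate 1, SOX1 had 3 endoderm counts, and ES cells were higher by a ratio of 25.5 (95% counting interval 8.48 to 125). SIX6 had 49 counts over the ES libraries and none in endoderm, at least 17.5-fold lower against a floor of 3 counts over the group. PAX6 stood at 0.519 ± 0.068 and 0.578 ± 0.180 CPM and did not pass. Of 11 neural crest and surface ectoderm genes 4 rose and 6 fell (median -1.54, camera adjusted p = 0.35), with MSX1 up by 3.66 and MSX2 up by 2.95, while KRT7, GRHL3 and GABRP fell (log2 fold changes of -3.97, -3.21 and -3.15).

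Of 10 trophoblast and amnion genes 3 rose and 4 fell (median -0.50, camera adjusted p = 0.38). Of these GATA3 rose by 0.50, and GATA2 fell by 1.14. Of 13 endothelial and blood genes 6 rose and 4 fell (median 0.07, camera adjusted p = 0.45). VWF rose from 0.886 ± 0.080 to 59.5 ± 4.6 CPM, whereas TIE1 and LMO2 fell (log2 fold changes of -1.39 and -1.39). Of 15 fibroblast and stromal genes 10 rose and 4 fell (median 1.61, camera adjusted p = 0.054). This list passed without endoderm replicate 2 or 3 (camera adjusted p of 0.049 and 0.048), and with all 6 libraries had an adjusted p of 0.54 with an estimated correlation. The matrix genes COL5A1 and COL6A1 and the intermediate filament VIM rose by 3.44, 2.53 and 3.08, while THY1, which ES cells also carry, fell from 616 ± 21.0 to 122 ± 8.3 CPM. Among germ cell genes 9 of 11 fell and 2 rose (median -1.84, camera adjusted p = 0.029, and adjusted p = 0.23 with an estimated correlation). The germ cell list shares 4 genes with the pluripotency list and 2 with the definitive endoderm list, so it is not separate evidence from those. DAZL fell from 5.46 ± 0.11 to 0.0385 ± 0.0420 CPM, a log2 fold change of -6.83, while PRDM1, which germ cell and endoderm share, rose by 6.06. Without endoderm replicate 2, DAZL had 1 endoderm count, and ES cells were higher by a ratio of 303 (95% counting interval 54.0 to 11978). With genes of mean CPM of at least 5 alone, the germ cell list had a median of -0.80 and a camera adjusted p of 0.34. Of 39 HOX genes 2 could be tested. HOXB1 fell by 2.94 and HOXB13 rose by 1.74, with an adjusted p of 0.013 (edgeR) that became 0.052 and a log2 fold change of 1.09 without ES replicate 3, and 2.67 without ES replicate 2.

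Each list of signalling genes held members that rose and members that fell. For NODAL, Activin and TGF-beta, 18 of 26 tested members rose and 8 fell (median 0.58, camera adjusted p = 0.013, and adjusted p = 0.19 with an estimated correlation). NODAL itself went from 80.4 ± 3.8 to 255 ± 9.4 CPM, and its inhibitors LEFTY1 from 105 ± 20.8 to 1274 ± 60.6 and LEFTY2 from 62.8 ± 10.6 to 772 ± 40.3. INHBA had 69 counts over the ES libraries and 2 in endoderm. For canonical WNT, 20 of 29 rose and 7 fell (median 1.32, camera adjusted p = 0.0020, and adjusted p = 0.38 with an estimated correlation). The WNT list shares 6 genes with the primitive streak list and 1 with the definitive endoderm list, so it is not separate evidence from those. The secreted inhibitor DKK1 rose by 8.24, while SFRP2 and the receptor FZD7 fell (log2 fold changes of -2.06 and -1.04). RNF43 and LEF1 did not pass, at log2 fold changes of 0.18 ± 0.11 and 0.81 ± 0.43 (SE). For BMP, 18 of 22 rose and 3 fell (median 0.95, camera adjusted p = 0.00027, and adjusted p = 0.23 with an estimated correlation). BMPER, which binds BMPs, rose by 3.72, BMP7 fell by 0.76 and ID3 did not pass at 112 ± 10.2 and 115 ± 5.8 CPM.

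For FGF and ERK feedback, 13 of 25 rose and 9 fell (median 0.10, camera adjusted p = 0.45). The ERK feedback genes IER3 and DUSP4 rose by 5.18 and 4.58, while FGF2, an ES cell growth factor, and FGF19 fell (log2 fold changes of -2.20 and -1.41). For retinoic acid, 9 of 16 rose and 4 fell (median 0.29, camera adjusted p = 0.19). The degrading enzyme CYP26A1 rose from 2.15 ± 0.31 to 698 ± 10.4 CPM and CYP26B1 from 0.891 ± 0.180 to 3.57 ± 0.18, while the reductase DHRS3 and the synthesis enzyme ALDH1A1 fell (log2 fold changes of -3.28 and -1.71). CRABP1 stood at 83.0 ± 3.5 and 78.1 ± 6.7 CPM and did not pass, but did without endoderm replicate 1 (adjusted p = 0.045, edgeR). For chemokine and Eph or ephrin guidance, 13 of 22 rose and 7 fell (median 1.39, camera adjusted p = 0.067). PLXNA2 and NTN1 rose by 5.67 and 4.52. CXCL12, the ligand of CXCR4, fell from 64.7 ± 4.7 to 15.4 ± 1.7 CPM and CXCL5 fell by 3.09.

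Genes of the epithelial to mesenchymal transition were split, with 16 of 27 higher and 10 lower (median 0.43, camera adjusted p = 0.12). N-cadherin (CDH2) went from 35.6 ± 1.0 to 449 ± 19.9 CPM, while E-cadherin (CDH1) remained at 165 ± 3.0 CPM against 246 ± 5.8 in ES cells. The transcription factors ZEB2 and ZEB1 rose by 5.36 and 4.41, from 0.0857 ± 0.0478 and 0.261 ± 0.034 CPM. The claudins CLDN3 and CLDN4 and the integrin ITGA6 fell (log2 fold changes of -2.56, -2.24 and -2.11). ITGB1 did not pass at 623 ± 40.7 and 612 ± 28.2 CPM.

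Chromatin regulators showed single large changes within lists that went both ways. Of 15 DNA methylation genes 8 rose and 6 fell (median 0.25, camera adjusted p = 0.45), and DNMT3L and TET2 rose by 3.20 and 1.31 while TET1 fell by 1.12. Of 40 Polycomb and Trithorax subunits 21 rose and 14 fell (median 0.18, camera adjusted p = 0.45). PHC1 fell from 1157 ± 25 to 252 ± 12.6 CPM and JARID2 from 569 ± 13.9 to 143 ± 2.0, while the H3K27 demethylase KDM6B rose from 4.92 ± 0.45 to 62.9 ± 2.2. ASH2L and KMT2B did not pass, at log2 fold changes of -0.01 ± 0.06 and -0.05 ± 0.06 (SE), and KMT2B did without ES replicate 2 (adjusted p = 0.030, edgeR). Of 16 imprinted genes 10 rose and 2 fell (median 0.35, camera adjusted p = 0.067), and PHLDA2 rose by 1.19 while MEST fell by 0.53. The imprinted list passed without endoderm replicate 3 (camera adjusted p = 0.039), and with all 6 libraries had an adjusted p of 0.38 with an estimated correlation.

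Cell cycle genes changed little in size. Of 36 tested, 10 rose, 15 fell and 11 did not pass, and none changed by over 2-fold (median -0.06, camera adjusted p = 0.41). RRM2 rose by 0.74 and BUB1B and MCM3 fell (log2 fold changes of -0.92 and -0.80). TOP2A stood at 437 ± 30.1 and 453 ± 28.8 CPM and did not pass, but did without ES replicate 2 (adjusted p = 0.030, edgeR). Among CDK inhibitors and p53 targets 9 of 24 rose and 14 fell (median -0.36, camera adjusted p = 0.23). The p53 targets CDKN1A, RRM2B and PHLDA3 fell (log2 fold changes of -2.43, -1.85 and -1.69), with CDKN1A going from 75.4 ± 3.5 to 14 ± 1.9 CPM, while CDKN2B rose by 3.77 from 0.130 ± 0.084 CPM and GADD45A by 1.13.

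Most cholesterol synthesis and uptake genes rose. Of 24 tested members 23 rose, 11 of them by over 2-fold, and PMVK fell by 0.48 (median 0.88). HMGCS1, an early enzyme of the pathway, went from 257 ± 18.2 to 694 ± 40.0 CPM, and STARD4 and MVD rose by 1.22 and 1.22. The camera adjusted p was 6.89e-07, with adjusted p = 0.19 with an estimated correlation. Most nuclear-encoded respiratory chain genes fell. Of 39 tested 32 fell, none by over 2-fold, and 2 rose (median -0.33), and SDHA and COX7C fell (log2 fold changes of -0.97 and -0.96) while ATP5H rose by 0.31. The camera adjusted p was 3.46e-05, with adjusted p = 0.30 with an estimated correlation. Of 23 glycolysis genes 8 rose and 11 fell. Their median was -0.01 and their mean 0.02, and camera gave a downward adjusted p of 0.45. Hexokinase HK1 fell from 666 ± 16.8 to 270 ± 3.7 CPM, the lactate exporter SLC16A3 and the glucose transporter SLC2A3 rose by 2.00 and 1.43, and GAPDH and PGAM1 did not pass. Of 20 hypoxia genes 10 rose and 3 fell (median 0.21, camera adjusted p = 0.058), and BHLHE40 and BNIP3 rose by 4.71 and 1.95 while ADM fell by 0.73. PGK1 did not pass at 591 ± 16.6 and 617 ± 15.7 CPM, but did without ES replicate 2 (adjusted p = 0.046, edgeR). The hypoxia list passed without ES replicate 2, endoderm replicate 2 or endoderm replicate 3 (camera adjusted p of 0.045, 0.049 and 0.048), and with all 6 libraries had an adjusted p of 0.26 with an estimated correlation.

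Genes of the unfolded protein and integrated stress response rose in 17 of 18 tested members (median 0.63), with DDIT3, PPP1R15A and MANF up by 1.995, 1.565 and 1.197 and ATF3 not past the threshold at 14.3 ± 1.0 and 15.7 ± 0.6 CPM. The camera adjusted p was 3.46e-05, with adjusted p = 0.19 with an estimated correlation. Of 16 immediate early and heat shock genes, which respond to handling, 8 rose and 4 fell (median 0.13, camera adjusted p = 0.23). EGR1 and DUSP1 rose by 1.30 and 1.23, IER2 fell by 0.28, and HSPA8 and JUN did not pass. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and so track how mRNA was selected, rose in 10 of 11 tested members (median 1.43, camera adjusted p = 0.0022, and adjusted p = 0.38 with an estimated correlation). HIST1H2BK and HIST1H1C, which can be polyadenylated, went from 7.34 ± 0.35 to 100 ± 3.3 CPM and from 7.12 ± 0.52 to 59.2 ± 2.6. HIST1H1E did not pass, at 0.687 ± 0.184 and 0.662 ± 0.521 CPM, with a log2 fold change of -0.05 that became -0.95 without endoderm replicate 1. These genes form a family of near-identical copies, so single values are uncertain.

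Control lists stood close to 0. Of 46 ribosomal protein genes 2 rose and 18 fell, all by small amounts (median -0.07, camera adjusted p = 0.12), and adjusted over the list alone 1 rose and 14 fell. With library size alone as the scaling, 1 rose and 27 fell. RPL10 rose by 0.28 and RPL13A fell by 0.22. RPL13A, RPL10 and others of this family have processed pseudogenes that can share reads. Of 15 reference genes 7 rose and 3 fell (median 0.10, camera adjusted p = 0.46). GAPDH stood at 4081 ± 166 and 4090 ± 111 CPM and RPLP0 at 2654 ± 77.3 and 2682 ± 29.9, neither past the threshold, while SDHA and HPRT1 fell (log2 fold changes of -0.97 and -0.71) and YWHAZ rose by 0.39. None of the 15 mitochondrially encoded genes was matched by symbol, so that list was not analysed here. For the other lists tested, the counts adjusted over the list alone equalled those given.

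**Figure D2:**
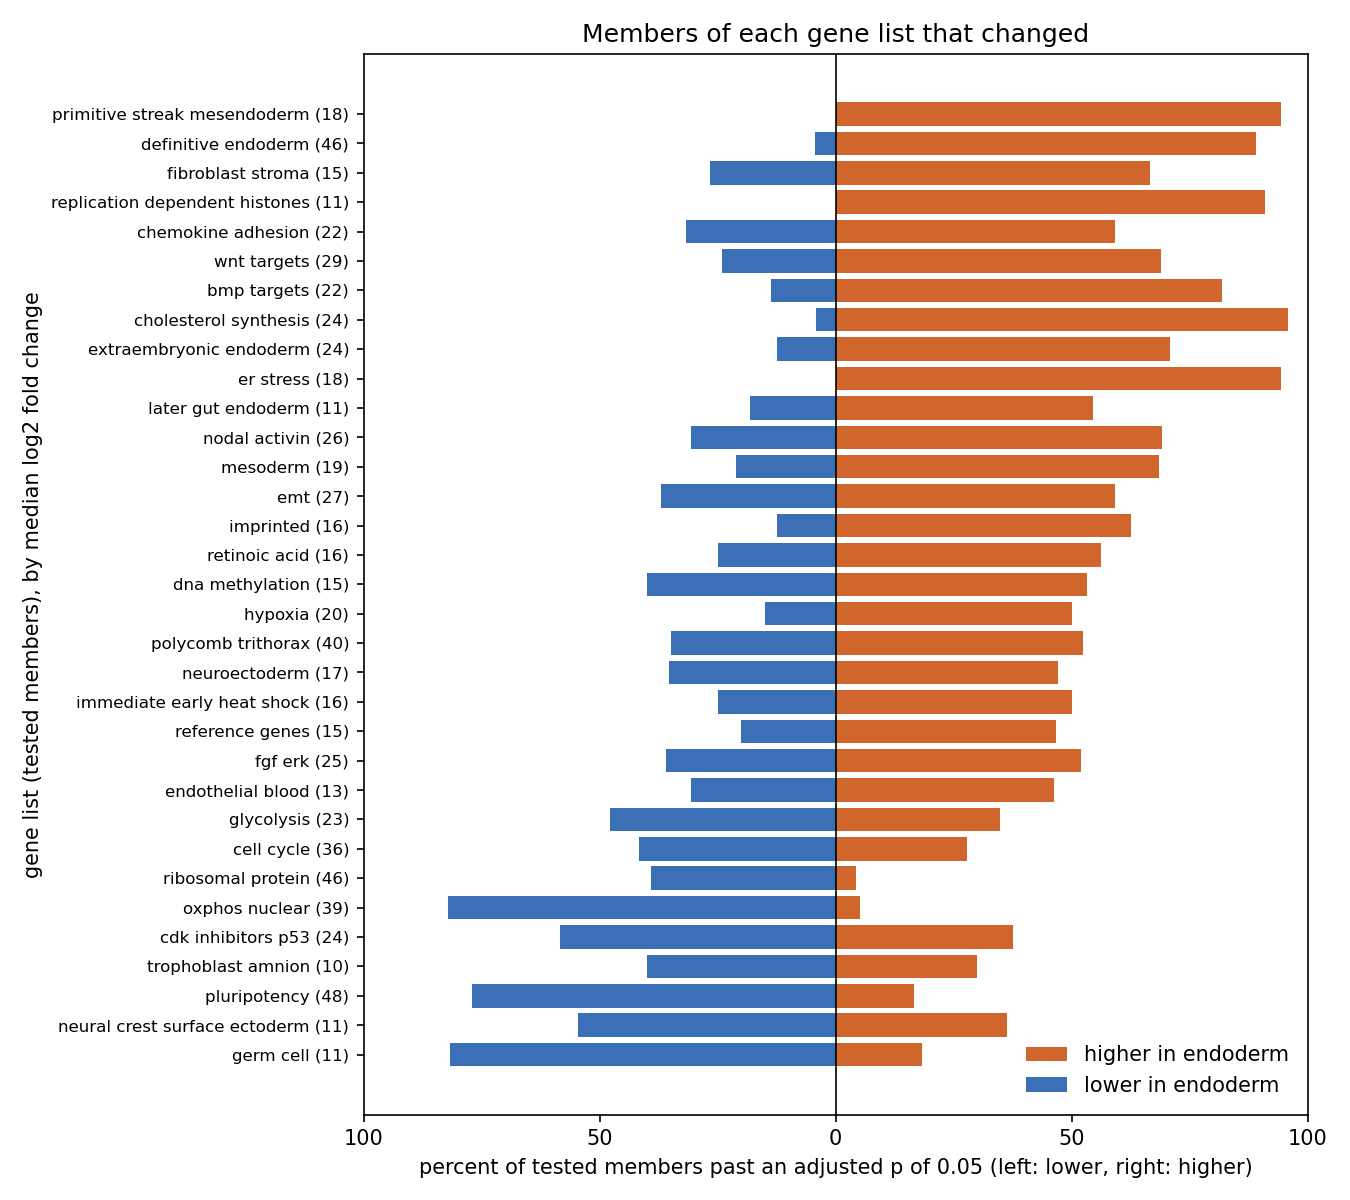
For each of the 33 gene lists with 3 or more tested members (number in brackets), the bars give the percent of members higher in endoderm (orange, right) and lower (blue, left) at an adjusted p of 0.05, and lists are ordered by median log2 fold change. Primitive streak, definitive endoderm, cholesterol synthesis, stress response and histone lists lie almost wholly on the right, and the germ cell, pluripotency and respiratory chain lists mostly on the left.

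Over the 33 lists, 9 lay above and 3 below other genes at an adjusted p of 0.05 with the preset correlation of camera. With an estimated correlation none did, so the statements on lists rest on counts of single genes. That setting does not isolate correlation, since p rose also where the estimate lay under the preset of 0.01. For NODAL and Activin the estimate was 9.16e-05, and the unadjusted camera p rose from 0.0042 to 0.033. The loss of calls therefore does not show how strongly the genes of a list are correlated. Of all 16331 tested genes 5821 were higher and 5751 lower, 70.9% in all. Counts near these shares do not set a list apart from other genes. With 3 libraries per group and a biological coefficient of variation of 5.25% between replicates, changes well below 2-fold passed the test.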

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

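The counts of higher and lower genes remained within 1.5 times under every alternative run, and no called gene or list named in the text turned its direction. Over 2450 pairs of a named gene and an alternative, 9 lost their call and 10 gained one. With DESeq2 as the test 5515 genes were higher and 5440 lower, and 94.6% of the main calls were kept in the same direction. Leaving out a library gave 5460 to 5951 higher and 5355 to 5829 lower genes, and over 2-fold 1760 to 1847 higher and 1767 to 1857 lower. The 2-fold counts moved only with a mean CPM of at least 5, to 871 higher and 754 lower, since fewer genes were tested (11687). Testing against a fold of 2 (glmTreat) left 1227 and 1179. Library size alone shifted the median log2 fold change by -0.04. The number of lists past the threshold was 12, became 0 with an estimated inter-gene correlation and 31 with fry, which asks another question, and was 12 to 16 without a library. Single lists near the threshold (stromal, mesoderm, hypoxia, guidance, ribosomal) passed under some scalings or filters. List tests were not run with DESeq2. With the replicate number as a block, 5991 genes were higher and 5901 lower, 1746 and 1736 over 2-fold, with 12 lists, and SALL4 and SOX9 passed. The numbers gave no sign of a pairing: deviations of same-numbered libraries from their group means correlated at 0.10, 0.09 and -0.11. Differently numbered pairs across the groups ran from -0.22 to 0.16. So few libraries cannot exclude a pairing. Depth limits genes near 1 count, such as the ES levels of the most strongly induced genes.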

Other observations

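The gene families below and all tests in this part except those of splits of the libraries and of the 6-library transformation were chosen after the values were seen. Genes were grouped by the stem of their symbol into 431 families of at least 6 tested members. Several families that no fixed list covers as a whole moved largely one way. All 9 tested kallikrein-type serine proteases (KLK) fell (median log2 fold change -1.33), among them KLK5 by 2.49, and 13 of 16 synaptotagmins (SYT) fell (median -1.26), with SYT6 going from 26.7 ± 1.2 to 3.82 ± 0.23 CPM (mean ± SD, n = 3) and SYT4 rising by 1.45. All 6 tested serine protease inhibitors of clade B (SERPINB) rose (median 1.73), led by SERPINB9, an inhibitor of granzyme B, from 19 ± 0.4 to 739 ± 18.5 CPM.

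Of 13 annexins (ANXA) 10 rose and 1 fell (median 0.89), with ANXA2 going from 222 ± 3.9 to 514 ± 17.8 CPM. Of 12 keratin genes (KRT) 10 rose and 1 fell (median 1.58), the latter being KRT7, a member of fixed lists above. KRT8 went from 669 ± 47.4 to 1593 ± 67.0 CPM and KRT18 from 525 ± 14.6 to 706 ± 22.9, and 3 of the others are KRT16 pseudogenes that share reads. Mitochondrial ribosomal proteins fell by small amounts, 32 of 51 of the large subunit family (MRPL, median -0.26, 4 higher) and 21 of 30 of the small (MRPS, median -0.27, 3 higher). Directions of these families held with DESeq2 size factors and with library size alone. With the preset correlation 10 families passed camera at an adjusted p of 0.05, and with an estimated correlation 0 did (adjusted p = 0.999 for each family named here), so the counts describe single genes.

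Splitting the 6 libraries into 3 and 3 in other ways is possible in 10 ways in all, too few for a share under 0.05. The real split gave 11572 genes past the threshold and the highest of the other splits 0 (1 of 10 splits with as many). Over 2-fold it gave 3488 against 0, again 1 of 10. For lists past the camera threshold the real split gave 12, and 2 of 10 splits gave as many, the highest other giving 14. The other splits gave 6 to 14 lists while calling no gene. Each of them was uneven, such as ES replicates 1 and 2 with endoderm replicate 1 against the remaining libraries. Part of the difference between ES cells and endoderm was therefore kept between the sides, and the rest added to the spread within them. The numbers of genes and lists in these splits thus do not show how many pass without a difference between groups.

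All 10 tested metallothionein genes fell (median -4.70), with summed levels of 716 ± 29 CPM in ES cells and 33.7 ± 2.8 in endoderm. Some of the 10 are pseudogenes that can share reads with the others, so their falls are not independent. The tables argue against lower recovery of short transcripts, since 451 other genes whose longest transcript is at most 829 nt, the longest of the 10 by the median over a gene's transcripts, had a median log2 fold change of -0.0177 (bootstrap interval -0.08 to 0.02), with -0.131 for the 123 of them with at least 10 CPM in a group, and -0.0081 and -0.0807 for 2 wider sets (2465 genes by median transcript, and 2193 with a longest transcript of at most 1727 nt). Reads passed between paralogs would leave the sum in place, but it was 21.3-fold lower. A hypothesis that remains open is that the induction medium held less available metal than the ES medium: SLC30A1, a zinc exporter that responds to metal with these genes, fell by 1.25, and SLC39A10, a zinc importer expected to rise at low zinc, fell by 0.34. Medium and cell state cannot be told apart here, because every endoderm library had both.

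Among 11 genes with a log2 fold change above 8 and at least 50 CPM in endoderm, 11 were highest in ES replicate 3 of the ES libraries. A candidate explanation is a small carry-over of endoderm reads or RNA into that library, which would add the same share of the endoderm level to each gene. The excess over the other ES libraries was 0.0818 ± 0.0115% (SE) of the endoderm level when pooled, and 0.0539 to 0.313% by gene. The chi-square p for a single share was 0.402. The errors behind this p include a dispersion fitted with ES replicate 3 itself, which widens them and favours a high p. A few differentiating cells in that culture would give the same picture, with all 11 genes highest there. These cannot be told apart, since differentiating cells allow a single share as well, and the limit on the errors of single genes (SE of 0.0265 to 0.126% here) beyond which the test was not taken to decide was set after its p was seen.

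In the deposited log2 table, 827 genes without a count in these libraries had values other than 0. A constant added before the logarithm would give such genes a single value in a library, but ES replicate 1 held 150 distinct values. A transformation fitted together with further libraries may be the source: the regularized log of these 6 libraries gave 0 such genes a value other than 0, but it sets them to 0 by construction, so this test decides nothing.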
